A study of Homo sapiens with 4 samples.

How the data were processed

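Total RNA from human fibroblasts was extracted with an RNeasy kit, and libraries were made from 10 ng RNA with Ion AmpliSeq Transcriptome Human Gene Expression reagents, per the labels' protocols. In that assay each gene is read from a short amplified target, so values describe that target and not the whole transcript. Sequencing was unstranded and ERCC spike-ins were named for normalization, per the labels' protocols. The genome build was hg19, per the submitters' processing notes, and the aligner and the counting tool are not given in the sources used here. The reference used here for transcript GC content and length was GENCODE release 29, on another build, so no coordinates are given. The treatment field of every sample gives the Poly I:C dose, while the day 0 sample is described as untreated in its characteristics and was taken as such. Samples were grouped by the day in their labels, 1 library per day for days 0, 2, 4 and 6.

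The deposited values are RPM per gene, scaled by the authors to the reads of each library. The table held 20812 entries, among them 10 spike-in entries, all with 0 reads in every library, so scaling by spike-ins was not possible. Gene names that had been turned into dates, 28 in number, were restored through their Entrez identifiers for 27. The 46 entries for Y-linked genes and XIST were left out of all results. In each library every value above 0 was a whole multiple of 1 step within 0.1 of a read for 100% of values, so whole read counts were recovered from the deposited values. One read was worth 0.161, 0.130, 0.152 and 0.129 RPM on days 0, 2, 4 and 6. The recovered totals were 6207215, 7671937, 6600397 and 7753178 reads, all above the depth per sample stated in the labels. Genes with at least 1 read numbered 14187, 14480, 14491 and 14690. The 10 most abundant genes took 13.0, 11.4, 11.4 and 10.4% of the reads.

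Ratios between days were taken on the scale log2(RPM + 1) for 9750 genes with a mean of at least 5 RPM over the 4 libraries, which understates ratios of low genes. A gene was counted as higher or lower at a ratio of at least 2-fold on that scale. Folds printed for single genes are plain ratios of RPM, and fold intervals are exact (Clopper-Pearson) 95% intervals of the share of the 2 libraries' recovered reads. An upper limit of 3 reads was taken for a count of 0. No replicate test could be made. No p-value was computed across genes, apart from an exact binomial test on the recovered reads, which compares 2 libraries and not the conditions.

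The gene lists, 28 with 484 genes in all of which 1 is not in the table, were interferon-stimulated genes, double-stranded RNA sensing, NF-kB targets and cytokines, MHC class I antigen presentation, glycolysis, hypoxia-inducible factor targets outside glycolysis, components of that factor's pathway, the TCA cycle with pyruvate dehydrogenase, oxidative phosphorylation, the pentose phosphate pathway, citrate export with fatty acid synthesis, cholesterol synthesis, contractile genes with targets of transforming growth factor beta, cell cycle, p53 targets with senescence, the integrated stress response, immediate early with heat shock genes, histone acetyltransferases with deacetylases, DNA methylation enzymes, pluripotency factors, fibroblast markers, endothelial markers and receptors and response genes for factors of the medium. Markers of other cell types covered keratinocytes, leukocytes, melanocytes with nerve sheath, lymphatic endothelium and pericytes with smooth muscle. For each list with at least 3 members averaging at least 1 RPM, among 12103 such genes, the median log2 ratio was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression. The percentile describes these libraries only.

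The named genes followed a rule. It took the 10 highest and 10 lowest ratios for each treated day against day 0, and the 5 highest and 5 lowest for day 4 against day 2 and day 6 against day 4. It added up to 6 members of each list with the largest ratios, and always HIF1A, TLR3, NOS2, SLC25A1, ACLY, IFNB1, PECAM1, CDH5 and KDR. This gave 203 genes, of which a part is named in the text. The grouping, the size rule, the lists, the named-gene rule and the first set of alternative settings were fixed before the data were examined.

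That first set held TMM factors (edgeR 4.0.16), median-of-ratios size factors (DESeq2 1.42.0), pseudocounts of 0.5 and 5, no filter, a mean of at least 20 RPM, thresholds of 1.5-fold and 4-fold, a counting interval wholly beyond 2-fold, and list means in place of medians. Both factor tools were used only for scaling of the recovered counts. TMM factors were 0.918, 0.992, 1.04 and 1.06 for days 0, 2, 4 and 6. Alternatives added later were centring of the ratios within 20 bins of transcript GC content, known for 9462 genes or 97.0% of those tested, centring on the median of all genes, the exact binomial test and leaving out 1 treated day.

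The procedure was tested on simulated reads for 9750 genes with 200 genes given known folds. For day 2 against day 0, 98.0% of genes simulated at 3-fold and 42.0% of those at 2-fold were counted, and 0 of 9550 unchanged genes were. For day 4 the shares were 98.0 and 30.0% with 2 unchanged genes, and for day 6 they were 98.0 and 46.0% with 3. The counting intervals held the simulated fold for 95.2, 95.7 and 95.3% of genes. These simulated reads held counting error only, so they do not give the rate of false calls between real libraries. Overlaps between comparisons that share the day 0 library were set beside 100 simulations of unchanged libraries, which hold counting error only. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.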

Results

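Human fibroblasts were kept in EGM2, an endothelial growth medium, and exposed to Poly I:C, a synthetic double-stranded RNA that activates innate immune receptors, at 30 ng/ml. Transcripts were counted with a targeted amplicon panel in cells on day 0, before treatment, and after 2, 4 and 6 days. The series title places the experiment in work on how innate immune activation alters metabolism during nuclear reprogramming and on the part of the transcription factor HIF1α. There was 1 library per day, 4 in all, so no difference below has a replicate check and no p-value is given for it. Untreated cells on days 2, 4 and 6 were not analysed here, so time in culture and Poly I:C cannot be separated in any comparison with day 0. The libraries held 6207215 reads on day 0, 7671937 on day 2, 6600397 on day 4 and 7753178 on day 6. Levels are in RPM, reads scaled to the library's total, and each fold is given with its exact (Clopper-Pearson) 95% counting interval in brackets. These intervals cover the counting error of reads only. Genes named for large ratios were selected on those ratios, and the intervals do not allow for that selection. Amplicon reads without molecular identifiers are not independent molecules, so the intervals can be too narrow even for the sampling of molecules.

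The first comparison asked what differed after 2 days. Transcripts of glycolysis and of other targets of the hypoxia-inducible factors were lower than on day 0, transcripts of the tricarboxylic acid (TCA) cycle were higher, and interferon-stimulated genes as a group stood close to their starting level. HIF1A, which encodes the oxygen-regulated subunit of hypoxia-inducible factor 1, stood at 386 RPM against 174 RPM on day 0, 2.23-fold higher [2.08 to 2.39]. SLC2A1, the glucose transporter GLUT1, was 1.85-fold lower [1.79 to 1.91], and BNIP3, a hypoxia-responsive mitophagy receptor gene, was 2.19-fold lower [2.07 to 2.32]. SUCLA2, a subunit of succinyl-CoA synthetase, was 2.58-fold higher [1.82 to 3.72].

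Of 22 measured glycolysis genes, 18 lay below their day 0 level on day 2 and 0 were as much as 2-fold lower. Their median log2 ratio was −0.24, at percentile 0.03 of 10000 random lists of the same size matched on mean expression. The neuronal enolase gene ENO2 was 1.89-fold lower [1.52 to 2.35], and SLC16A3, the lactate exporter MCT4, was 1.62-fold lower [1.56 to 1.69]. The 25 measured hypoxia-inducible factor targets outside glycolysis had a median of −0.20 at percentile 0.04, with 17 below day 0 and 2 at least 2-fold lower. PDK1, which encodes a kinase that inhibits pyruvate dehydrogenase, went the other way at 2.24-fold higher [1.26 to 4.16]. Among 21 genes of the TCA cycle and pyruvate dehydrogenase, 16 lay above day 0, with a median of 0.43 at percentile 99.99, and PDHB, a pyruvate dehydrogenase subunit, was 2.01-fold higher [1.43 to 2.87]. The 39 nuclear-encoded subunits of oxidative phosphorylation had a median of 0.21 at percentile 98.5, with 30 above day 0 and COX7B, a cytochrome c oxidase subunit, 2.04-fold higher [1.78 to 2.34].

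NF-kB targets and cytokines had a median of −0.19 at percentile 0.52 over 16 measured members, but among members averaging at least 20 RPM the median of −0.15 lay inside the central 95% of random lists. Immediate early and heat shock genes, which respond to handling of cells, had a median of −0.35 at percentile 0.04, with the early response genes IER3 at 1.88-fold lower [1.65 to 2.16] and EGR1 at 1.56-fold lower [1.41 to 1.72]. The 33 measured interferon-stimulated genes had a median of 0.15 at percentile 67.9, with 24 above day 0, 3 at least 2-fold higher and 2 at least 2-fold lower. The higher members were MX2 at 4.59-fold [1.33 to 24.4], SAMD9 at 3.24-fold [1.69 to 6.69] and SAMD9L at 2.29-fold [1.48 to 3.62], and the lower ones were OAS1 at 9.92-fold lower [1.33 to 439] and BST2, the virus-tethering protein tetherin, at 2.66-fold lower [1.53 to 4.77]. MX2, SAMD9, SAMD9L and OAS1 lie outside the named-gene rule and were chosen after their values were seen. Of these, MX2, SAMD9 and OAS1 averaged under 5 RPM. TPM1, an actin-binding tropomyosin, was 2.39-fold higher [2.27 to 2.52]. The genes with the highest ratios included FAM175A, a component of a BRCA1 complex, at 7.89-fold [3.81 to 18.9], the SUMO protease gene SENP6 at 6.14-fold [3.35 to 12.3] and the translation factor gene DENR at 5.51-fold [3.67 to 8.59]. SNORA64, a small nucleolar RNA, stood at 478 RPM against 66.7 RPM, 7.17-fold higher [6.47 to 7.95], and its unstranded reads cannot be told from those of a gene that overlaps it. The lowest ratios included the ETS transcription factor gene ETV4 at 3.01-fold lower [1.97 to 4.70] and CH25H, cholesterol 25-hydroxylase, at 2.88-fold lower [1.86 to 4.58].

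Of 9750 genes averaging at least 5 RPM, 270 were at least 2-fold higher on day 2 and 20 at least 2-fold lower, and with TMM factors between libraries these counts were 182 and 38. The median over all tested genes was 0.11 on the log2 scale. Ratios also ran with transcript GC content, with a Spearman correlation of −0.37 across 9462 genes, which are not independent replicates. After the ratios were centred by GC content, the median was −0.19 for glycolysis, −0.23 for the other hypoxia-inducible factor targets, 0.38 for the TCA cycle and 0.22 for oxidative phosphorylation, and the log2 ratio of HIF1A was 0.94, just under the 2-fold threshold, against 1.15 before.

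**Figure D1:**
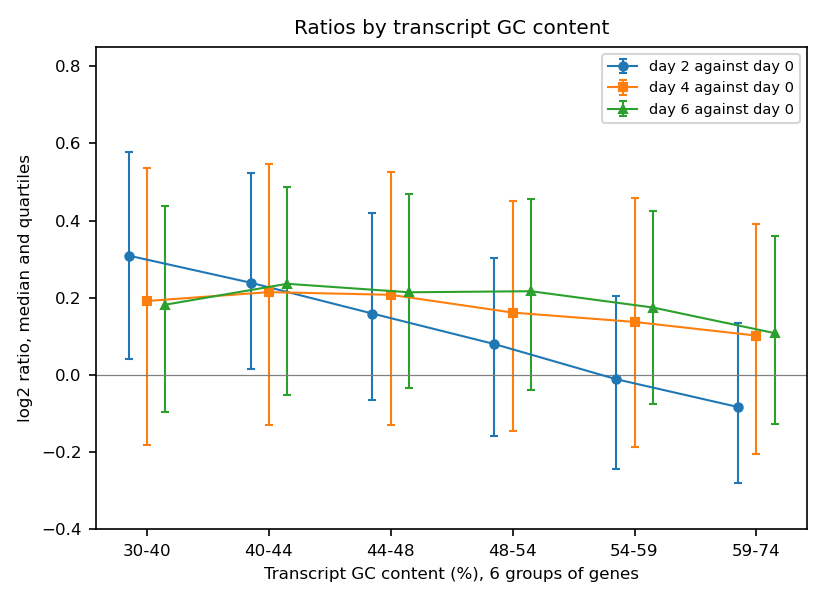
Median log2 ratio against day 0 (points) and quartiles (bars) for 6 groups of 1577 genes ordered by transcript GC content, in percent on the x axis, for days 2, 4 and 6 with 1 library each. For day 2 the medians run from 0.31 in the group lowest in GC to −0.08 in the group highest in GC, and for day 6 they lie between 0.11 and 0.24.

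The comparison of day 4 with day 0 asked what differed after the longer exposure. Cell cycle transcripts were higher than on day 0, contractile genes and genes of the integrated stress response were lower, and glycolysis genes remained below their starting level as a group. RRM2, the ribonucleotide reductase subunit that limits DNA synthesis, stood at 109.8 RPM against 22.7 RPM, 4.84-fold higher [4.03 to 5.83]. ELN, which encodes elastin, stood at 883 RPM against 4321 RPM, 4.90-fold lower [4.76 to 5.04]. MTHFD2, a mitochondrial one-carbon enzyme induced by the integrated stress response, was 3.18-fold lower [2.95 to 3.43].

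Among 26 cell cycle genes, 25 lay above day 0 and 11 were at least 2-fold higher, with a median of 0.93 at percentile 100, where matched random lists had a median of 0.18. PCNA, the DNA polymerase clamp, was 3.16-fold higher [2.54 to 3.96], the mitotic kinase gene CDK1 2.99-fold higher [2.37 to 3.80], and PRC1, needed for cytokinesis, 10.9-fold higher [5.91 to 22.5]. In the list of 14 contractile genes and targets of transforming growth factor beta, 13 lay below day 0 and 4 were at least 2-fold lower, with a median of −0.74 at percentile 0. ACTA2, smooth muscle actin, was 2.40-fold lower [2.30 to 2.51], and CNN1, calponin, was 2.07-fold lower [1.88 to 2.28]. In the integrated stress response list, 13 of 16 members lay below day 0 and 4 were at least 2-fold lower, with a median of −0.41 at percentile 0.02. CHAC1, a glutathione-degrading enzyme, was 3.59-fold lower [2.90 to 4.48], and SESN2, which encodes the stress sensor sestrin, was 2.38-fold lower [2.11 to 2.69].

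The glycolysis median on day 4 was −0.31 at percentile 0.02, with 15 of 22 members below day 0. SLC16A3 was 2.66-fold lower [2.53 to 2.79] and SLC2A1 was 2.18-fold lower [2.11 to 2.26]. The other hypoxia-inducible factor targets had a median of −0.21 at percentile 0.225, with DDIT4, an inhibitor of mTORC1 signalling, 2.21-fold lower [1.97 to 2.49]. PDK1 was again higher, at 2.93-fold [1.67 to 5.40]. In the interferon-stimulated list 30 of 33 members lay above day 0 and 7 were at least 2-fold higher, with a median of 0.48 at percentile 99.8. IFI44 was 5.20-fold higher [3.08 to 9.30], and MX1, an antiviral GTPase, was 2.27-fold higher [1.78 to 2.91]. Over the members averaging at least 20 RPM, however, the interferon median of 0.37 lay inside the central 95% of random lists. Immediate early and heat shock genes had a median of −0.38 at percentile 0.12, with the AP-1 genes FOS 3.66-fold lower [2.14 to 6.58] and JUNB 2.58-fold lower [2.32 to 2.88], while the chaperone gene HSPH1 was 2.24-fold higher [1.91 to 2.63]. The medians of the TCA cycle, at 0.16 and percentile 49.9, of oxidative phosphorylation, at 0.12 and percentile 43.5, and of NF-kB targets, at 0.38 and percentile 91.9, lay inside the central 95% of random lists on day 4. Those of the TCA cycle and oxidative phosphorylation lay below the median of 0.17 over all tested genes, so their signs depend on the scaling.

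The highest ratios on day 4 included CCL7, a monocyte chemokine, at 8.55-fold [4.58 to 17.7], APOD, apolipoprotein D, at 5.94-fold [5.00 to 7.11] and KIAA0101, a PCNA-binding factor, at 5.74-fold [4.06 to 8.32]. The lowest included the hair keratin gene KRT34, whose reads can be shared with paralogs, at 5.25-fold lower [4.13 to 6.74], the transcription factor gene KLF9 at 5.08-fold lower [4.37 to 5.92] and the stress-induced gene NUPR1 at 4.71-fold lower [4.32 to 5.13]. In all, 491 genes were at least 2-fold higher and 178 at least 2-fold lower. The median over all tested genes was 0.17, and with TMM factors the counts were 279 higher and 318 lower, so which direction held more genes turned with the scaling.

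On day 6, the longest exposure, interferon-stimulated genes had the highest list median, contractile genes the lowest, and glycolysis genes were no longer below day 0 as a group. IFI6, an interferon-induced mitochondrial protein gene, stood at 1995 RPM against 130.2 RPM on day 0, 15.3-fold higher [14.3 to 16.5]. In the interferon-stimulated list 32 of 33 members lay above day 0 and 17 were at least 2-fold higher, with a median of 1.06 at percentile 100, where random lists had a median of 0.21. IFI44 was 6.55-fold higher [3.94 to 11.6], USP18, a brake on interferon signalling, 4.04-fold [2.57 to 6.62], MX1 3.88-fold [3.11 to 4.88], BST2 3.76-fold [2.69 to 5.36] and OAS3, a double-stranded RNA-activated enzyme, 3.39-fold [2.49 to 4.68].

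The 13 measured genes of double-stranded RNA sensing all lay above day 0 and 0 were as much as 2-fold higher, with a median of 0.41 at percentile 95.6. DDX58, the sensor RIG-I, was 1.81-fold higher [1.53 to 2.14]. The median of antigen presentation by major histocompatibility complex (MHC) class I was 0.39 at percentile 96.8, with the peptide-trimming enzyme gene ERAP2 at 2.53-fold higher [2.01 to 3.20] and HLA-B at 1.95-fold higher [1.70 to 2.24], although reads of HLA genes can be shared between near-identical copies. NF-kB targets had a median of 0.38 at percentile 91.6, with 11 of 16 members above day 0 and 5 below. CCL2, a monocyte chemokine, was 2.20-fold higher [2.06 to 2.34]. The interleukin gene IL6 went the other way. It was 2.17-fold lower than day 0 on day 4 [1.53 to 3.11] and 1.535-fold lower on day 6 [1.14 to 2.08].

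All 14 contractile genes and targets of transforming growth factor beta lay below day 0 on day 6 and 5 were at least 2-fold lower, with a median of −0.71 at percentile 0. ELN stood at 480.4 RPM, 8.99-fold lower [8.69 to 9.31], ACTA2 was 3.34-fold lower [3.19 to 3.50], and TAGLN, the actin-binding protein transgelin, was 2.29-fold lower [2.21 to 2.37]. Markers of pericytes and smooth muscle, which overlap in function with that list, had a median of −0.31 at percentile 0.1. MYH11, smooth muscle myosin, was 6.60-fold lower [3.70 to 12.7]. Over the pericyte and smooth muscle markers averaging at least 20 RPM, the median of −0.19 lay inside the central 95% of random lists. The integrated stress response median was −0.49 at percentile 0, with PSAT1, a serine synthesis enzyme, 2.13-fold lower [1.99 to 2.27]. The cell cycle median was 0.66 at percentile 100, with 25 of 26 members above day 0 and 6 at least 2-fold higher.

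Glycolysis genes had a median of 0.31 at percentile 97.2 on day 6, just inside the central 95% of random lists. SLC2A1, at 1406 RPM, was still 1.14-fold lower than on day 0 [1.11 to 1.17], and ENO2 was 1.46-fold higher [1.24 to 1.74]. The other hypoxia-inducible factor targets had a median of 0.19 at percentile 62.9, which came to −0.01 with TMM factors. HIF1A stood at 298 RPM, 1.72-fold above day 0 [1.60 to 1.85]. On day 6 the medians of the TCA cycle, at 0.33 and percentile 93.95, of oxidative phosphorylation, at 0.16 and percentile 56.7, and of immediate early and heat shock genes, at 0.03 and percentile 13.4, also lay inside the central 95% of random lists. Those of oxidative phosphorylation and of immediate early and heat shock genes lay below the median of 0.19 over all tested genes, so their signs depend on the scaling. Of 11 leukocyte markers only CD68, CD14 and LAPTM5 averaged at least 1 RPM, and their median was 1.06 at percentile 99.2, against 0.0 over all members, most of which had 0 reads. CD68, a lysosomal protein gene also transcribed in fibroblasts, was 2.10-fold higher [1.82 to 2.43]. The highest ratios on day 6 also included APOD at 9.87-fold [8.35 to 11.7], AKR1C1, a steroid-reducing enzyme with near-identical paralogs, at 9.84-fold [6.00 to 17.2], XDH, xanthine dehydrogenase, at 9.71-fold [4.74 to 23.1] and CLEC3B, tetranectin, at 6.22-fold [4.98 to 7.84].

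In all, 332 genes were at least 2-fold higher on day 6 and 83 at least 2-fold lower, and with TMM factors these counts were 166 and 150. Median-of-ratios factors gave 155 and 162, so which direction held more genes turned with the scaling. The median over all tested genes was 0.19.

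**Figure D2:**
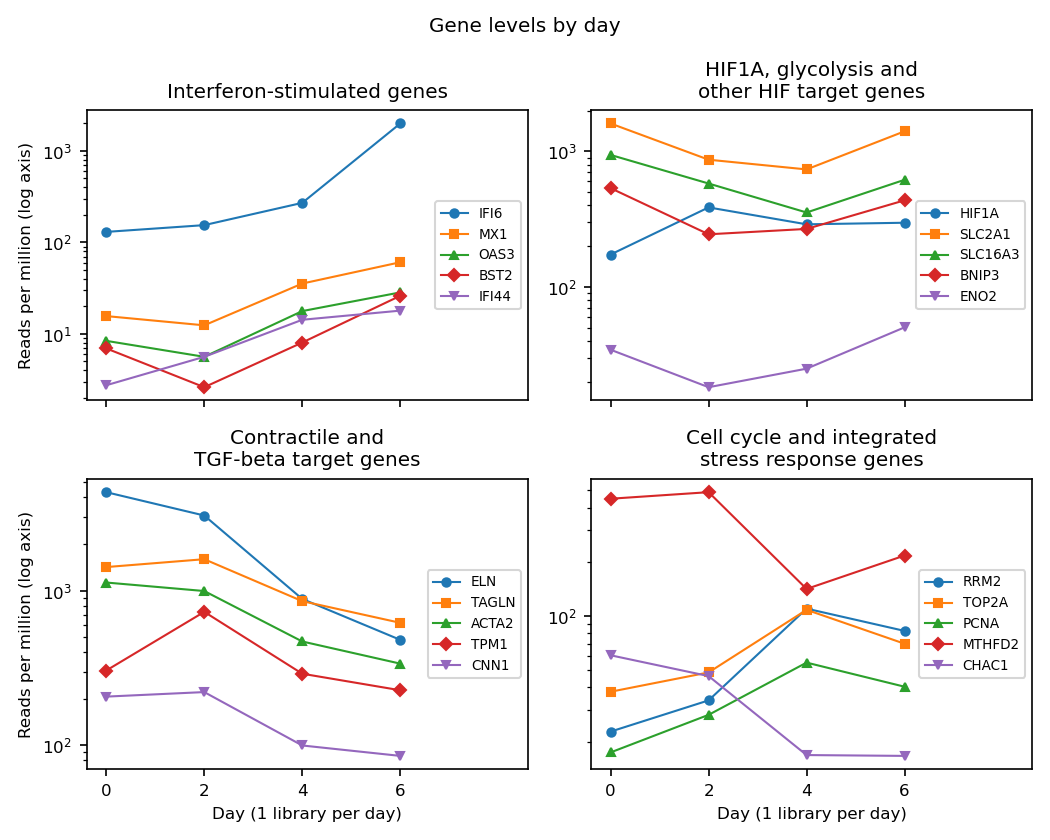
Levels of 20 genes in RPM (log y axis) against day (x axis), 1 library per point, with lines joining the days. IFI6 stands at 130.2, 154, 270.4 and 1995 RPM on days 0, 2, 4 and 6, while ELN stands at 4321 RPM on day 0 and 480.4 RPM on day 6 and SLC2A1 is lowest on day 4 at 736 RPM.

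Between day 2 and day 4, contractile genes and integrated stress response genes were lower and cell cycle genes higher. All 14 contractile genes were lower on day 4, with a median of −0.83 at percentile 0, and ELN was 3.46-fold lower [3.36 to 3.56]. All 16 integrated stress response genes were lower, with a median of −0.56 at percentile 0, and all 26 cell cycle genes were higher, with a median of 0.94 at percentile 100. NF-kB targets had a median of 0.44 at percentile 99.7. CCL7, a chemokine gene outside that list, was 8.94-fold higher [5.00 to 17.4]. Interferon-stimulated genes had a median of 0.24 at percentile 97.54, and oxidative phosphorylation subunits −0.11 at percentile 1.38. SNORA64 was 8.81-fold lower [7.90 to 9.85] and the transcription factor gene CEBPD was 5.95-fold lower [4.42 to 8.18]. In all, 243 genes were at least 2-fold higher on day 4 than on day 2 and 246 at least 2-fold lower, and with TMM factors these counts were 193 and 320. The correlation of these ratios with GC content was 0.23 across genes.

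Between day 4 and day 6, glycolysis genes and interferon-stimulated genes were both higher. Glycolysis genes had a median of 0.49 at percentile 100, with 18 of 22 higher on day 6, and SLC2A1 was 1.91-fold higher [1.85 to 1.98]. The other hypoxia-inducible factor targets had a median of 0.33 at percentile 99.99, with 23 of 25 higher and BNIP3 1.63-fold higher [1.53 to 1.72]. Interferon-stimulated genes had a median of 0.65 at percentile 100, and IFI6 was 7.38-fold higher [7.03 to 7.75]. IRF1, an interferon-induced transcription factor, was 3.62-fold higher [2.84 to 4.67] and HLA-E 3.04-fold higher [2.88 to 3.22], but both stood below day 0 on day 4, IRF1 at 12.4 RPM against 24.0 and HLA-E at 238 RPM against 532. Against day 0 they were 1.88-fold [1.54 to 2.29] and 1.36-fold [1.30 to 1.42] higher on day 6. Immediate early and heat shock genes, taken as a sign of handling, had a median of 0.52 at percentile 100 over the same interval, with JUNB 2.37-fold higher [2.13 to 2.64]. Cell cycle genes were lower, with a median of −0.34 at percentile 0.01, and PRC1 was 2.46-fold lower [1.80 to 3.40]. Contractile genes had a median of −0.26 at percentile 0.56 and pericyte and smooth muscle markers −0.37 at percentile 0.52, while citrate export and fatty acid synthesis had 0.34 at percentile 98.8 and endothelial markers 0.41 at percentile 98.5. In all, 105 genes were at least 2-fold higher on day 6 than on day 4 and 24 at least 2-fold lower.

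Between day 2 and day 6, glycolysis genes had a median of 0.55 at percentile 100, with 20 of 22 higher on day 6, and ENO2 was 2.76-fold higher [2.27 to 3.38]. The other hypoxia-inducible factor targets had a median of 0.33 at percentile 99.9. Interferon-stimulated genes had a median of 0.87 at percentile 100, and IFI6 was 12.9-fold higher [12.2 to 13.7]. Oxidative phosphorylation subunits had a median of −0.14 at percentile 0.03, contractile genes −0.81 at percentile 0 and integrated stress response genes −0.69 at percentile 0. Pericyte and smooth muscle markers went the same way as the contractile genes, with a median of −0.61 at percentile 0 and 3 of 9 at least 2-fold lower. Cell cycle genes had a median of 0.56 at percentile 100, MHC class I antigen presentation 0.32 at percentile 98.6, NF-kB targets 0.34 at percentile 97.9 and medium factor receptors 0.37 at percentile 98.8. In all, 232 genes were at least 2-fold higher and 161 at least 2-fold lower, and with TMM factors these counts were 180 and 223. The correlation of these ratios with GC content was 0.30 across genes.

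Some genes were fixed for reporting because of the study's question, whatever their values. SLC25A1, the mitochondrial citrate carrier, stood at 61.7, 59.8, 55.0 and 69.8 RPM on days 0, 2, 4 and 6, and its fold from day 0 on day 6 was 1.13 [0.990 to 1.29]. The median over all tested genes was 0.19 on the log2 scale on day 6, so the direction of this fold depends on the scaling. ACLY, which turns cytosolic citrate into acetyl-CoA, stood at 116, 143, 117 and 132 RPM, 1.23-fold above day 0 on day 2 [1.12 to 1.35]. IFNB1, the interferon beta gene, and NOS2, inducible nitric oxide synthase, had 0 reads on all 4 days. A count of 0 allows up to 3 reads, a level of 0.483 RPM on day 0, 0.391 on day 2, 0.455 on day 4 and 0.387 on day 6. TLR3, an endosomal receptor of double-stranded RNA, stood at 0.391 RPM on day 2, which is 3 observed reads and not a count of 0. It did not exceed the level of 3 reads on any day. Among endothelial genes, CDH5, vascular endothelial cadherin, had 0 reads on every day. KDR, a receptor of vascular endothelial growth factor, stayed under the level of 3 reads. PECAM1 had 0 reads on days 0 and 2 and stood at 1.36 RPM on day 4 and 1.81 RPM on day 6. Only 9 of 27 endothelial markers averaged at least 1 RPM, and their medians were −0.09, −0.01 and 0.48 on days 2, 4 and 6, the last at percentile 92.2.

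The other lists stayed inside the central 95% of random lists on all 3 treated days, as did the lists above on treated days for which no median against day 0 is given. Fibroblast markers and extracellular matrix genes had medians of 0.15, 0.17 and 0.16 on days 2, 4 and 6. Within that list S100A4 was 2.23-fold higher on day 6 [2.14 to 2.33] and the transcription factor gene TWIST1 2.58-fold lower [2.15 to 3.10]. Citrate export and fatty acid synthesis had medians of 0.25, 0.01 and 0.23, with ACACA, the first enzyme of fatty acid synthesis, 2.93-fold higher on day 2 [2.05 to 4.27]. Cholesterol synthesis had medians of 0.13, 0.39 and 0.34, and the pentose phosphate pathway 0.09, 0.11 and 0.07. Components of the hypoxia-inducible factor pathway had medians of −0.09, 0.04 and 0.07, and targets of p53 and senescence genes 0.02, −0.02 and 0.04. Histone acetyltransferases and deacetylases had medians of −0.01, 0.29 and 0.19, with the acetyltransferase gene EP300 2.01-fold higher on day 2 [1.68 to 2.40] and 2.04-fold on day 6 [1.71 to 2.44]. Other members went the other way, with 14 of 20 above day 0 and 6 below on day 6, and 1 member at least 2-fold lower. DNA methylation and demethylation enzymes had medians of 0.06, 0.31 and 0.34. Only 3 of 10 pluripotency factors were measured, with medians of −0.09, 0.47 and 0.33, and KLF4 was 1.68-fold higher on day 6 [1.44 to 1.97]. Receptors and response genes for factors of the growth medium had medians of −0.07, 0.04 and 0.03, with the glucocorticoid-induced gene FKBP5 2.22-fold higher on day 4 [1.65 to 3.04]. The 3 measured keratinocyte markers had medians of 0.17, 0.10 and −0.15. Of the melanocyte and nerve sheath markers 2 were measured, and of the lymphatic endothelial markers 0, too few for a median. Over all lists, 19 of 78 medians against day 0 lay outside the central 95% of random lists. For lists of randomly drawn genes 3.9 would lie outside. Members of a list can vary together and all these medians share the day 0 library, so the excess does not measure a difference between conditions. With TMM factors or median-of-ratios size factors, the medians of the pentose phosphate pathway turned negative on all 3 days, as did those of fibroblast markers, hypoxia-inducible factor components and medium factor receptors on days 4 and 6. The same scalings turned the medians negative for p53 targets on days 2 and 6, for DNA methylation enzymes on day 2, and for citrate export and keratinocyte markers on day 4. Median-of-ratios factors alone did so for cholesterol synthesis on day 2 and histone acetyltransferases and deacetylases on day 6. With GC centring, endothelial medians turned positive on days 2 and 4, those of the histone enzymes and pluripotency factors on day 2 did so as well, and the medians of hypoxia-inducible factor components on day 4 and of medium factor receptors on day 6 turned negative.

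**Figure D3:**
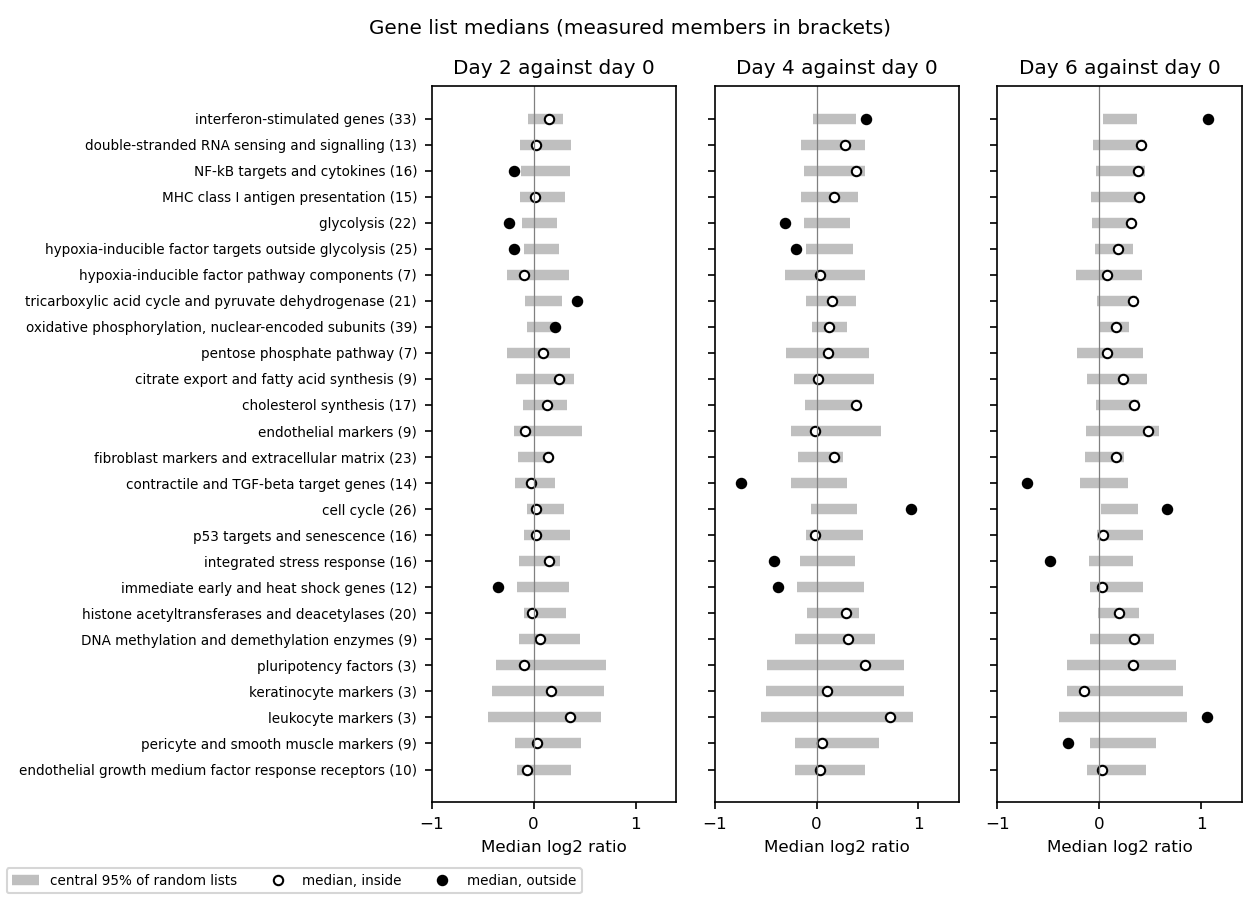
Median log2 ratio of each of 26 gene lists (x axis, 1 line per list with its number of measured members) on days 2, 4 and 6 against day 0, with 1 library per day. Grey bars span the central 95% of 10000 random lists matched on mean expression, and filled points lie outside them, as for interferon-stimulated genes at 1.06 on day 6 and contractile genes at −0.74 on day 4.

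Across the time course, 1027 genes were at least 2-fold from day 0 on at least 1 treated day. Day 4 was the farthest day for 378 higher and 149 lower genes, day 6 for 230 and 63, and day 2 for 194 and 13. Without the day 4 library the number of genes was 642. Medians over all tested genes against day 0 were 0.11, 0.17 and 0.19 on days 2, 4 and 6, so a shift of the whole scale may add to the higher counts. Genes at least 2-fold higher on day 6 whose level also stood above the day before on each day numbered 126, among them IFI6 and APOD, and 36 genes ran the opposite way, among them ELN and ACTA2. Days 2 and 4 shared 119 genes at least 2-fold higher than day 0, where independent lists would share 13.6 and simulated unchanged libraries shared a mean of 0.07. For days 4 and 6 the numbers were 165, 16.7 and 0.05, and for days 2 and 6 they were 59, 9.19 and 0.06. Days 4 and 6 shared 49 genes at least 2-fold lower, against 1.52 for independent lists and 0 in simulated unchanged libraries. Because all these ratios use the 1 day 0 library, part of each excess may come from that library.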

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

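The GC centring, the median centring, the exact binomial test and the counts without 1 treated day were chosen after the data were seen. No paired analysis was possible because each day has replicate 1 only. Scaling by the ERCC spike-ins was not run because all 10 entries have 0 reads. The depth limits low genes most, since 3 reads are 0.483 RPM on day 0. With a pseudocount of 0.5 all 91 main results held their direction and call. Every list median outside the central 95% of random lists against day 0 was also outside it with GC centring, which changes little on days 4 and 6, where the correlations with GC content were −0.07 and −0.06. Where a count below moved with a threshold, filter or pseudocount, the alternative's own construction sets how many genes can pass, and in the other cases the cause was not tested.

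Counts are given as higher and lower genes for days 2, 4 and 6 against day 0, then for day 4 against 2, day 6 against 4 and day 6 against 2. At 1.5-fold they were 1202 and 301, 1818 and 711, 1452 and 362, 1018 and 955, 677 and 400, and 881 and 673, with 3848 genes on any treated day. At 4-fold they were 5 and 0, 19 and 7, 17 and 3, 11 and 8, 2 and 0, and 28 and 5, with 46 on any day. With the counting interval wholly beyond 2-fold they were 74 and 2, 170 and 67, 102 and 46, 96 and 87, 27 and 2, and 117 and 73. The exact binomial test, at an adjusted p under 0.05 and no fold threshold, gave 2737 and 1332, 3494 and 1653, 3489 and 1225, 2684 and 2163, 2015 and 1827, and 2616 and 1855. At a mean of at least 20 RPM they were 109 and 6, 230 and 113, 126 and 51, 106 and 131, 49 and 9, and 105 and 92, with 495 on any day. With a pseudocount of 5 they were 105 and 4 for day 2, 218 and 104 for day 4, 134 higher for day 6, then 114 and 123, 40 and 4, and 127 and 98, with 502 on any day. With no filter 52 genes were lower on day 2, 761 higher on day 4 and 599 higher on day 6, then 409 higher for day 4 against 2, 191 and 66 for day 6 against 4 and 427 higher for day 6 against 2, with 1618 on any day.

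With TMM factors 38 genes were lower on day 2, while day 4 had 279 and 318 and day 6 had 166 and 150. Median-of-ratios factors gave 156 and 42, 264 and 340, and 155 and 162 against day 0. Median centring gave 175 and 39, 287 and 312, and 165 and 149. GC centring gave 172 higher genes on day 2. Without day 4, 642 genes were at least 2-fold from day 0 on a treated day, against 870 without day 2 and 835 without day 6.

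Among list medians against day 0, means in place of medians put 5 more outside the central 95% of random lists, at 0.52 for double-stranded RNA sensing and 0.45 for MHC class I on day 6, 0.21 and 0.26 for fibroblast markers on days 2 and 4, and −0.14 for medium factor receptors on day 2. At a mean of at least 20 RPM, 3 medians came to lie inside, at 0.37 for interferon-stimulated genes on day 4, −0.15 for NF-kB targets on day 2 and −0.19 for pericyte markers on day 6. The same filter put 7 outside, at 0.71 for double-stranded RNA sensing, 0.47 for NF-kB targets, 0.42 for MHC class I, 0.44 for cholesterol synthesis and 0.39 for histone acetyltransferases and deacetylases on day 6, −0.10 for cell cycle on day 2 and −0.34 for p53 targets on day 4. A pseudocount of 5 put double-stranded RNA sensing at 0.35 and MHC class I at 0.39 on day 6 outside. With no filter the former lay outside at 0.41, and the leukocyte median on day 6 came to 0.0, because most of its members had 0 reads. Of the other results, 693 in number and mostly ratios of single named genes, 127 moved with TMM factors, 162 with median-of-ratios factors, 115 with median centring, 80 with a pseudocount of 5 and 38 with GC centring, and 0 called results changed direction.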

Other observations

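The counts of genes that stood apart on 1 day, the GC trend on day 2, the comparison with GC bins on day 6, the test for leukocyte RNA and the test of a shared hypoxia-inducible factor response were chosen after the results were seen.

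Several genes stood at least 2-fold beyond each of the other 3 libraries on a single day, with 1 library per day. No variation between cultures or library preparations could be measured for these counts. On day 6 these were 21 higher genes and 1 lower gene, TWIST1. The higher genes included ADH1B, an alcohol dehydrogenase, at 16.1 RPM on day 6 against 2.09 RPM on day 0, a 7.70-fold difference [4.34 to 14.9], and SRD5A2, a steroid reductase, at 13.0 RPM against 1.45 RPM, 8.98-fold higher [4.55 to 20.2]. RXFP1, a relaxin receptor, stood at 17.4 RPM against 4.51 RPM, 3.86-fold higher [2.55 to 6.03]. On day 4, 19 genes stood lower than on each other day and 6 higher. Among the lower genes were MRPL37, a mitochondrial ribosomal protein gene, at 56.4 RPM against 203 RPM on day 0, 3.60-fold lower [3.21 to 4.05], and BLOC1S1, a lysosomal trafficking gene, at 12.3 RPM against 43.8 RPM, 3.57-fold lower [2.78 to 4.63].

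Day 0 stood lower than every treated day for 52 genes and higher for 2. These counts were made on the deposited scale only. Medians over all tested genes against day 0 were 0.11, 0.17 and 0.19 on days 2, 4 and 6, so a shift of the whole scale may contribute. The lower genes included UBAP1, an endosomal sorting gene, at 5.96 RPM on day 0 and 24.8, 15.2 and 15.7 RPM on days 2, 4 and 6, and CCNL2, a cyclin linked to splicing, at 13.4 RPM on day 0 and 40.0, 73.3 and 28.8 RPM later. Day 2 alone was lower for 7 genes, among them BST2, ETV4 and CH25H, and higher for 18 genes, among them ZNF148, a zinc finger factor, at 13.4 RPM against 1.77 RPM on day 0.

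More genes were at least 2-fold higher than lower on day 2. After GC centring, 60.8% of the 265 higher genes with a known GC content were still at least 2-fold higher, which leaves open that a GC trend between the 2 libraries accounts for part of the excess. With TMM factors there were 4.79 higher genes per lower gene, and with the GC bins and the overall median both centred there were 3.32, so a shift of the whole scale may also contribute. These explanations and a difference between the days themselves cannot be told apart with 1 library per day.

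Interferon-stimulated genes were higher on day 6 than on day 0. Ratios for these days ran little with GC content, with a Spearman correlation of −0.057, so the median of 1.05 after GC centring is hardly a test. The highest median ratio of any transcript GC bin that holds a member was 0.249. That lies below the 95% order-statistic interval of the list's median of 1.06 [0.72 to 1.76], which treats the genes as independent. These values argue against a trend with transcript GC content as the cause. GC content of the amplified targets was not examined, so a trend with it stays open. The mean of the leukocyte transcripts PTPRC, LYZ, TYROBP, LAPTM5 and CD3E on day 6 was 0.542 RPM, which is 3.78% of the median difference of 14.3 RPM over the 33 interferon-stimulated genes. The measured leukocyte markers CD68, CD14 and LAPTM5 had a median of 1.06 at percentile 99.2 on day 6, so RNA from leukocytes stays open. The Poly I:C exposure and the days in culture both stay open as well and were not tested apart.

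Glycolysis genes were lower on days 2 and 4 than on day 0, and higher on day 6 than on day 2. After GC centring, 89.2% of the difference between the day 6 and day 2 medians was left. This argues against a trend with transcript GC content as the whole cause, while GC content of the amplified targets was not examined. A response shared with other hypoxia-inducible factor targets may contribute and stays open, because the median of those targets, at percentile 99.9 for day 6 against day 2, was examined only after their daily medians were seen. Those targets lay at percentile 62.9 for day 6 against day 0, and HIF1A was 1.30-fold lower on day 6 than on day 2 [1.23 to 1.37]. The HIF1A value is a transcript level, and the protein was not measured, so it does not decide the question. Handling, time in culture and Poly I:C stay open as untested.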
